A study of Mus musculus with 16 samples.

How the data were processed

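Total RNA of CD4+CD8+ thymocytes from fetal thymic organ culture had been hybridised to 16 Affymetrix mouse expression arrays, on which each probe set reads 1 stretch of a transcript. The labels placed the arrays in 6 groups: BDC2.5/B6g7 without peptide (n = 3), BDC2.5/B6g7 at 16 h of peptide (n = 3), wild-type B6g7 (n = 2), BDC2.5/NOD without peptide (n = 3), BDC2.5/NOD at 16 h of peptide (n = 3) and wild-type NOD (n = 2).

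The table deposited by the authors held 1 intensity per probe set and array on a linear scale, from 7.77 to 14085. The authors had scaled the arrays to each other before deposit, and the method of scaling, of background correction and of probe set summary is not given in the sources used here. The array medians of the log2 values lay within 0.11 of each other, below the limit of 0.2 set for rescaling, so the authors' scale was kept. Values were taken to log2 with no pseudocount. The number of arrays limits the precision.

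Of 12488 probe sets, 66 control probe sets were left out and 12422 were tested. Of these, 10833 named 1 gene, 396 named several and 1193 named none in the platform annotation. The 1-gene probe sets named 8251 distinct genes. Gene IDs matched the mouse RefSeq table for 10817 of these probe sets, and 0 symbols changed. Chromosomal positions were not used here.

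Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend). The fit held all 16 arrays and 1 mean per group, so that the small groups shared 1 spread per probe set, with 10 residual and 3.60 prior degrees of freedom. The comparisons were the peptide response in each strain, their mean and their difference, the strain difference (NOD minus B6g7) without peptide, at 16 h and in wild-type cells, and the transgene difference (BDC2.5 without peptide minus wild-type) in each strain. Benjamini-Hochberg adjustment ran within each comparison, and a probe set was called at an adjusted p under 0.05. All tests were two-sided. Values after ± are standard errors of the fit for log2 differences and standard deviations for group means.

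Gene lists were tested with limma's camera on the moderated statistics, with a preset inter-gene correlation of 0.01 and 1 probe set per gene (that with the highest mean over all arrays). Adjustment ran over the 24 lists of a comparison, and the test was repeated with an estimated correlation. There were 18 pathway and thymocyte lists and 6 lists of markers of other cell types: B cells, myeloid and dendritic cells, thymic epithelium, mesenchyme and endothelium, erythroid cells, and NK and innate lymphocytes. Members were also counted with p adjusted over the list alone.

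The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made after seeing the data. The rule named, among called 1-gene probe sets that were their gene's brightest, the 12 largest rises and the 12 largest falls with no overlap of the groups' arrays. It did so for each peptide response, for their difference (there without the overlap condition) and for the strain difference without peptide, and it named 6 each way in the other comparisons. It also named up to 4 members of each list with the smallest p, and 22 fixed genes whatever their values. Of these, Cd69 and Nfkb1 were not on the array, and 1 gene is not reported here. Other called probe sets named in the text were chosen after their values were seen.

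The titles number the arrays of each group. Same-numbered BDC2.5 arrays deviated together from their group means: across probe sets, which are not independent replicates, the correlation of their deviations was 0.639, 0.249 and 0.600 between the peptide groups of B6g7 and 0.608, 0.581 and 0.793 between those of NOD. Between strains it was 0.777, 0.165 and 0.842 without peptide and 0.577, 0.234 and 0.569 at 16 h. Deviations cancel within a group, so a shared departure of the arrays numbered 3 would alone make those numbered 1 and 2 deviate together. Differently numbered arrays were not compared, so these values do not establish pairs. The numbers were taken to pair the 12 BDC2.5 arrays as an assumption, not from the labels. A fit with the replicate number as a block was an alternative. For the transgene differences the correlations were 0.695 and 0.058 in B6g7 and 0.678 and -0.499 in NOD. The arrays numbered 1 thus deviated together there and those numbered 2 did not. The replicate block still grouped the wild-type arrays numbered 2 with the BDC2.5 arrays numbered 2.

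The size of the response in NOD relative to B6g7 was the orthogonal (total least squares) slope through the origin of the NOD on the B6g7 log2 changes, over the probe sets called for the mean response. Its two-sided p, on the size of the log slope, came from an exact permutation of the arrays between strains within each peptide state (400 assignments), after each probe set's mean strain difference was removed. After seeing the data, it was repeated with strains exchanged only between arrays of the same number and peptide state (64 assignments). Alternatives were a filter on the dimmest 40% of probe sets, quantile normalization, median centring, log2(value + 32), no intensity trend, robust eBayes, array weights (statmod 1.5.0), the replicate block, only the groups of a comparison in the fit, and each array left out in turn. Tables were handled with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1) and plots drawn with matplotlib 3.10.9.

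The pipeline was tested on simulated data with 12422 probe sets and the arrays of the B6g7 peptide comparison. It called 75% of 100 probe sets changed by 1 on the log2 scale and 96% of 100 changed by 2, with 5.49% false calls. A built-in slope of 0.6 came back as 0.588. The simulated noise was independent between arrays and between probe sets. It lacked the shared deviations of same-numbered arrays, so these rates cannot be carried over to the real arrays.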

Results

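The arrays measured gene expression in CD4+CD8+ (double-positive) thymocytes from fetal thymic organ culture, in which fetal thymus lobes are kept in a dish. BDC2.5 mice carry the T cell receptor (TCR) transgenes of a diabetogenic CD4 T cell clone. NOD mice develop autoimmune diabetes, and B6g7 mice carry the MHC haplotype of NOD on a C57BL/6 background. In each strain, 3 arrays came from BDC2.5 cells without peptide, 3 from BDC2.5 cells at 16 h of peptide and 2 from wild-type cells, which made 16 arrays. Median intensity per array lay between 54.7 and 59.1. The labels name neither the peptide nor its dose, and do not say whether the wild-type cultures had peptide. They also do not say that replicates are separate animals, and if they are not, the p-values measure technical spread.

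The first principal component held 57.9% of the variance of the 3000 most variable probe sets, and it did not follow strain, peptide or transgene. The 4 BDC2.5 arrays numbered 3 and the 2 wild-type arrays numbered 2 (the third-number arrays) took its highest values, from 6.73 to 37.7. In these 6 arrays the signal of the 3' minus the 5' probe set of beta-actin was 1.69 ± 0.25 on the log2 scale, against 2.67 ± 0.32 in the other 10. It was the lowest of its group in 6 of 6 groups (exact permutation p = 0.00309, the smallest that the 324 assignments can give). They made up 1 of 3 arrays in each BDC2.5 group and 1 of 2 in each wild-type group, so the peptide and strain comparisons were balanced for them and the transgene comparisons were not.

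**Figure D1:**
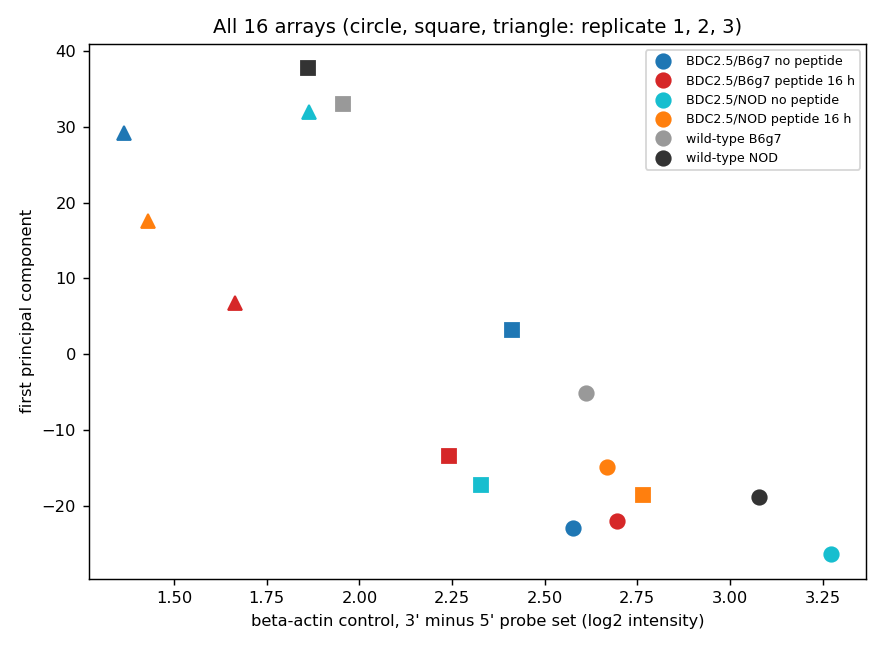
Each point is 1 of the 16 arrays, with the beta-actin 3' minus 5' log2 signal on the x axis and the first principal component on the y axis. The 6 third-number arrays (the 4 triangles and the 2 wild-type squares) sit at 6.73 or higher on the y axis.

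The first comparison asked what 16 h of peptide did to BDC2.5 thymocytes on the B6g7 background. Gadd45b, a stress- and NF-kB-induced gene, rose by its dimmer probe set, from a mean intensity of 24.6 to 152 (log2 2.63 ± 0.33, adjusted p = 0.0243, 3 of 3 same-numbered pairs up, n = 3 per group). The starting value lies below the array medians and the deposited table has no detection values, so the size of this rise is uncertain. This was the 1 probe set called, and it was named after its value was seen because the gene's brighter probe set gave 0.89 ± 0.29 without passing (adjusted p = 1). Nr4a1 (Nur77), an orphan nuclear receptor induced by TCR signals, went from 272 to 1195, which was 4.40-fold in 3 of 3 pairs, and missed the threshold (log2 2.14 ± 0.35, adjusted p = 0.107). Itm2a, a transmembrane protein gene linked to thymocyte selection, went from 296 to 1046 (1.82 ± 0.31, adjusted p = 0.107). With the replicate block it passed (adjusted p = 0.0410), but not with a block fitted within each strain.

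Bcl2l11 (Bim), the BH3-only death gene, gave 1.14 ± 0.26 in 3 of 3 pairs (adjusted p = 0.434) by its brightest probe set, while its other probe sets gave 0.06 and 0.57. Pdcd1 (PD-1), an inhibitory receptor, gave 1.81 ± 0.38 in 3 of 3 pairs (adjusted p = 0.378), with an SD of 1.12 among the 3 peptide arrays. Of the recombination genes of double-positive cells, Rag1 gave -1.10 ± 0.59, Rag2 -1.13 ± 0.37 and Dntt -0.74 ± 0.27, each at adjusted p = 1. Among the other fixed genes, Egr2 gave 0.64, Nab2 0.48, Egr1 0.15, Cd5 0.97, Cd28 -0.02, Il7r 0.81, Ccr7 0.37, Tnfrsf9 0.07 (1.54 by its dimmer probe set), Bcl2 0.03, Bcl2l1 -0.03, Nfkbia -0.06 and Fas -0.21, none of them called.

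limma called 1 of 12422 probe sets, higher with peptide, and 422 had an unadjusted p under 0.05, where chance alone gives 621. With the replicate block 877 did, so the count under 621 does not show that peptide had no effect. With that block limma called 3, the paired fit adding Itm2a and Smyd5 (a dimmer probe set chosen after its value was seen, log2 0.81, adjusted p = 0.0332 with the block). Neither passed with a block fitted within each strain. The count was 0 without any of the 3 arrays without peptide or the peptide arrays numbered 1 or 3, and 10 without the peptide array numbered 2. Leaving out the third-number arrays, chosen after seeing the data, gave 3.

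**Figure D2:**
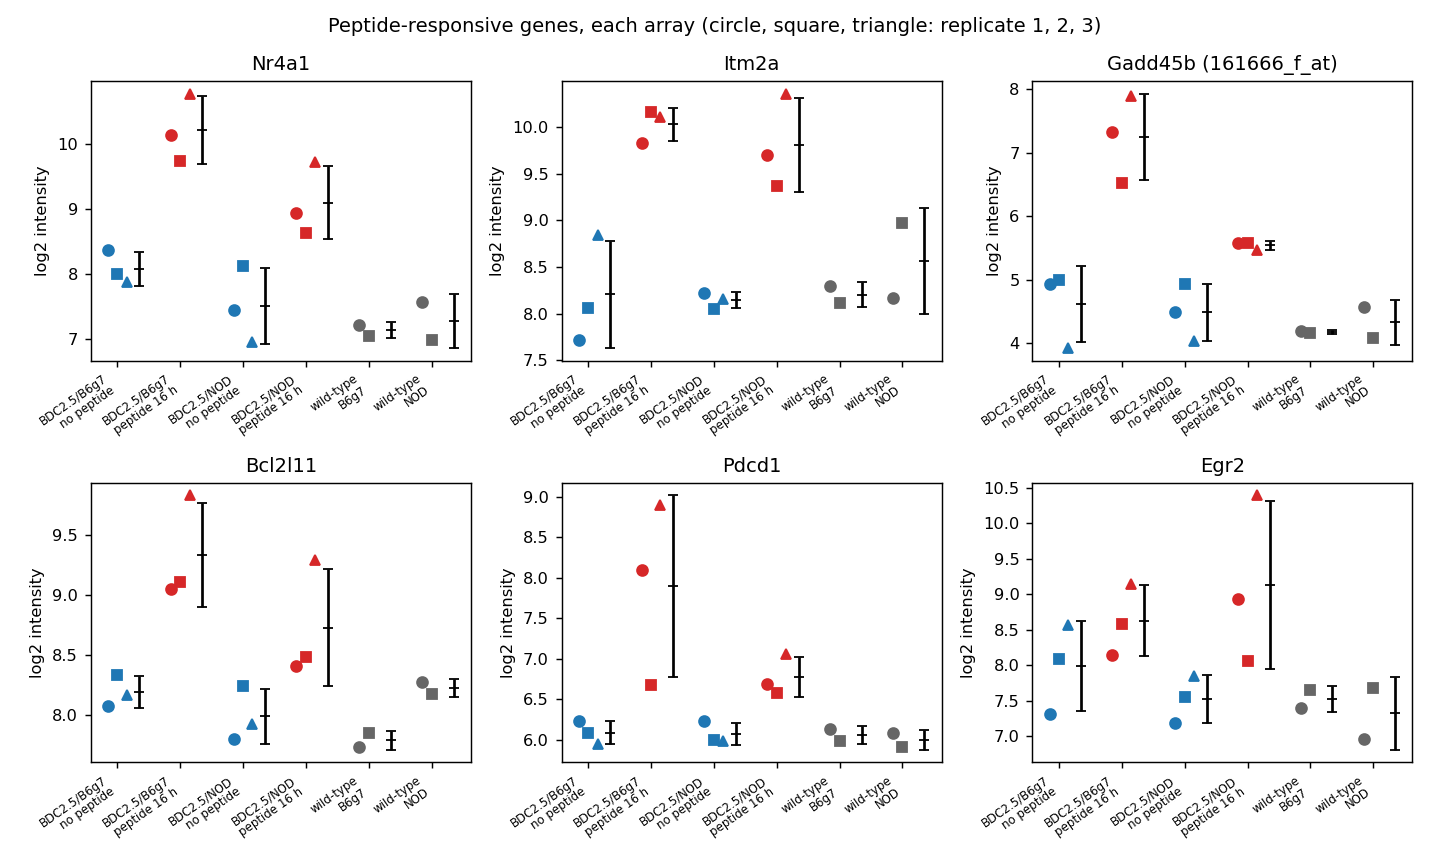
Each point is the log2 intensity of 1 array for Nr4a1, Itm2a, Gadd45b, Bcl2l11, Pdcd1 and Egr2 in the 6 groups, and the bar beside it is the group mean ± SD (n = 2 or 3). With peptide, Nr4a1 rose by 1.87 on average over both strains, with all 6 same-numbered pairs higher.

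As groups, genes of T cell activation rose in B6g7 with peptide. Of 29 measured activation receptors and cytokines, 27 were higher (median log2 0.33, camera adjusted p = 4.48e-14, and adjusted p = 0.0650 with an estimated correlation). No member passed over all genes, and 5 passed adjusted over the list alone: the TNF-family members Tnfrsf4 (OX40) at 0.83, Tnfrsf1b at 1.10 and Tnfsf11 (RANKL) at 1.35, with Pdcd1 and the inhibitory ligand Cd200. TCR immediate-early genes also rose, 19 of 26 being higher (median 0.16, adjusted p = 1.6e-07, and adjusted p = 0.0650 with an estimated correlation), and Nr4a1 and Irf4 (1.03 ± 0.21), a transcription factor graded with TCR signal strength, passed adjusted over the list alone. NF-kB pathway genes rose, 18 of 21 being higher (median 0.17, adjusted p = 0.000337, and adjusted p = 0.179 with an estimated correlation), with Relb and Nfkb2 (0.95) passing adjusted over the list alone. The NF-kB call was lost without the peptide array numbered 3 (adjusted p = 0.237). TCR feedback and calcium regulators, among them Nfatc1 at 1.47 ± 0.41, rose by the test (13 of 22 higher, adjusted p = 0.0203, and adjusted p = 0.159 with an estimated correlation), with 0 members passing either way. That call was lost without the no-peptide array numbered 1 (adjusted p = 0.311) or the peptide array numbered 3 (0.426).

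Growth and proliferation genes moved in opposite directions in B6g7. Ribosome biogenesis and nucleolar genes rose, 25 of 29 being higher (median 0.41, adjusted p = 2.34e-10, and adjusted p = 0.0833 with an estimated correlation). Examples by value were Ppan at 1.36 ± 0.45, Srm at 0.84 ± 0.24 and Odc1 at 0.64 ± 0.20. Cell cycle genes fell, 36 of 41 being lower (median -0.32, adjusted p = 2.34e-10, and adjusted p = 0.0833 with an estimated correlation). Ccnd3 (cyclin D3) gave -1.09 ± 0.24, lower in 3 of 3 pairs and passing adjusted over the list alone, and Cdk1 gave -0.59 and Aurka -0.53. Double-positive thymocyte genes fell, 13 of 18 being lower (median -0.29, adjusted p = 0.000271, and adjusted p = 0.128 with an estimated correlation), with Ets2 at -0.89.

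In B6g7, 6 further lists were called. Positive selection and maturation genes rose (17 of 25 higher, adjusted p = 0.0359, and adjusted p = 0.215 with an estimated correlation), and Itm2a passed adjusted over the list alone. Myeloid and dendritic cell markers rose (24 of 29 higher, median 0.08, adjusted p = 6.13e-05, and adjusted p = 0.159 with an estimated correlation), with Tyrobp at 0.61 and C1qa at 0.40 from intensities of 36.7 and 79.9. NK and innate lymphocyte markers rose (7 of 11, adjusted p = 0.0228, and adjusted p = 0.299 with an estimated correlation), led by Cd160 at 0.93. Chaperones (22 of 32 higher, adjusted p = 0.00484) and glycolysis genes (15 of 22 higher, adjusted p = 0.00729) rose, with adjusted p = 0.349 and 0.271 with an estimated correlation. Interferon-response genes were higher by the test (24 of 30, median 0.24, adjusted p = 0.0117, and adjusted p = 0.632 with an estimated correlation), but without the third-number arrays, a choice made after seeing the data, the median turned to -0.26 (adjusted p = 2.1e-10). Without the peptide array numbered 3, chaperones (adjusted p = 0.562), glycolysis (0.851) and maturation genes (0.695) lost their calls. Without the no-peptide array numbered 1, the same 3 lists (0.149, 0.0571 and 0.184) and interferon-response genes (0.355) lost theirs. Maturation genes (0.0548) and NK markers (0.191) did so without the no-peptide array numbered 3, and NK markers (0.107) without the peptide array numbered 1.

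The cell death lists did not shift as groups in B6g7. Of 25 pro-apoptotic genes, 10 were higher and 15 lower (adjusted p = 0.946). Adjusted over the list alone, Bcl2l11 and the death ligand Fasl (0.31 ± 0.09) passed upward and the caspase gene Casp6 (-0.69 ± 0.18) passed downward, with 0 passing over all genes. Of 19 anti-apoptotic genes, 9 were higher (adjusted p = 0.769), with a median of -0.01 and a mean of 0.01. Also without a call were TCR proximal signalling (adjusted p = 0.769, median -0.03 and mean 0.01), double-negative thymocyte genes (0.212), p53 targets (0.0758, median -0.18, and 0.0483 with the replicate block), oxidative phosphorylation (0.0758) and glucocorticoid-responsive genes (0.146). The markers of B cells (0.136), thymic epithelium (0.806), mesenchyme and endothelium (0.769) and erythroid cells (0.177) had no call either.

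The second comparison asked the same of BDC2.5 thymocytes of NOD mice. The largest values among the fixed genes were those of Egr2, an early TCR-induced factor, at 1.61 ± 0.49 (SD 1.18 among the peptide arrays) and Nr4a1 at 1.60 ± 0.35, from 182 to 550. Both were higher in 3 of 3 pairs, and both had adjusted p = 1. Itm2a gave 1.67 ± 0.31, from 283 to 897 (adjusted p = 0.641), and Gadd45b by its dimmer probe set gave 1.05 ± 0.33 (adjusted p = 1). Bcl2l11 gave 0.74 ± 0.26, Pdcd1 0.70 ± 0.38, Nab2 0.72 ± 0.18 and Cd5 0.83 ± 0.47. Dntt gave -0.54, Rag1 -0.41 and Rag2 -0.36. The probe sets of Bcl2 did not go together: a dimmer one gave 1.18 ± 0.21 (adjusted p = 0.641) and the brightest -0.12. limma called 0 probe sets, 0 with the replicate block, and 207 had an unadjusted p under 0.05, against 574 with the block.

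The TCR immediate-early genes rose in NOD with peptide, 19 of 26 being higher (median 0.18, camera adjusted p = 6.16e-08), and this call held with an estimated correlation (adjusted p = 0.0449). Nr4a1, Egr2 and Nab2 passed adjusted over the list alone, and 0 members over all genes. Positive selection and maturation genes rose (16 of 25, adjusted p = 5.11e-05, and adjusted p = 0.0449 with an estimated correlation), with Itm2a passing adjusted over the list alone. The other 6 calls had adjusted p = 0.404 to 0.534 with an estimated correlation. They were rises of ribosome biogenesis (24 of 29, median 0.17, adjusted p = 3.73e-05), activation receptors and cytokines (20 of 29, median 0.07, adjusted p = 0.00045), NF-kB genes (15 of 21, adjusted p = 0.00431), oxidative phosphorylation (24 of 34, adjusted p = 0.02) and interferon-response genes (28 of 30, median 0.32, adjusted p = 2.8e-07), and a fall of cell cycle genes (34 of 41, median -0.25, adjusted p = 4.08e-05). Without the no-peptide array numbered 3 in NOD, the activation (adjusted p = 0.129), NF-kB (0.0681), cell cycle (0.179) and oxidative phosphorylation (0.865) calls were lost, and the last also without the peptide array numbered 2 (0.0924). The other 16 lists were not called in NOD (adjusted p = 0.132 to 0.943), among them pro-apoptotic genes (0.343, median -0.02 and mean 0.01) and double-positive genes (0.427). The test pointed up against the sign of the median for double-negative genes (median -0.09), and for thymic epithelial markers and glucocorticoid-responsive genes, whose medians lay just below 0.

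**Figure D3:**
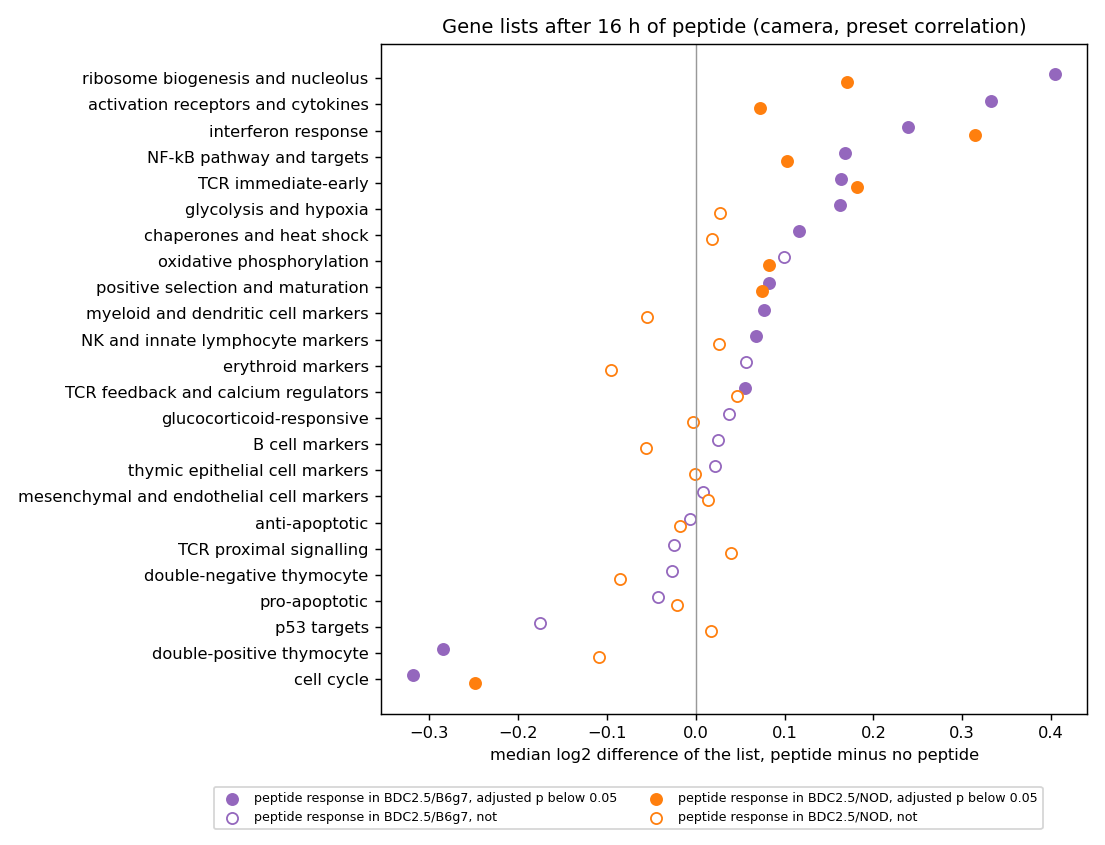
Each point is the median log2 difference of 1 gene list between peptide and no peptide, in BDC2.5/B6g7 (purple) and BDC2.5/NOD (orange), filled where camera with the preset correlation called the list. Ribosome biogenesis (0.41 and 0.17) and cell cycle genes (-0.32 and -0.25) were called in both strains.

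Averaged over both strains, 3 genes rose with peptide. Nr4a1 rose by 1.87 ± 0.25 (adjusted p = 0.0138), Gadd45b, by its dimmer probe set, by 1.84 ± 0.24 (adjusted p = 0.0136) and Itm2a by 1.74 ± 0.22 (adjusted p = 0.0136), and each was higher in 3 of 3 pairs of both strains. Bcl2l11 gave 0.94 ± 0.18 (adjusted p = 0.173), Pdcd1 1.25 ± 0.27 (0.326) and Nab2 0.60 ± 0.13 (0.308). These 3 genes were all that limma called, with 445 probe sets at an unadjusted p under 0.05. The replicate block called 7, adding Ephx1, Fos, Pprc1 and Mettl1, with 897 at an unadjusted p under 0.05. Leaving out single arrays gave 0 without the B6g7 peptide array numbered 1 or the NOD no-peptide array numbered 1, and 1 without the B6g7 no-peptide array numbered 2. It gave 5 and 10 without the B6g7 peptide arrays numbered 3 and 2.

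In the same average, 13 lists were called, of which 5 held with an estimated correlation. These were rises of TCR immediate-early genes (21 of 26, adjusted p = 1.95e-12, and 0.0246 with an estimated correlation), activation receptors (24 of 29, 1.92e-13), ribosome biogenesis (27 of 29, 1.97e-12) and maturation genes (17 of 25, 8.07e-05), and a fall of cell cycle genes (37 of 41, 1.97e-12). The last 4 had adjusted p = 0.0442 with an estimated correlation. Adjusted over the list alone, 8 immediate-early genes passed upward (Nr4a1, Ier2, Egr2, Gadd45b, Fos, Irf4, Nab2 and Myc) and the antiproliferative gene Btg2 passed downward, against 1 over all genes. The 8 calls lost with an estimated correlation (adjusted p = 0.109 to 0.404) were those of NF-kB (1.7e-05), interferon-response (6.82e-07), double-positive (0.00249), chaperone (0.00249), oxidative phosphorylation (0.00692), TCR feedback (0.00734), glycolysis (0.016) and myeloid genes (0.0421). Single arrays also ended some of these. Without the B6g7 peptide array numbered 3, calls ended for interferon-response (0.238), TCR feedback (0.0861), glycolysis (0.52), chaperone (0.17) and myeloid genes (0.0774). TCR feedback did so without the B6g7 no-peptide array numbered 1 (0.0674), glycolysis without that numbered 2 (0.0609) and myeloid markers without that numbered 3 (0.231) or the B6g7 peptide array numbered 1 (0.213). Without the NOD no-peptide array numbered 1, glycolysis (0.114), chaperone (0.124) and myeloid calls (0.0532) ended, and without that numbered 2 the myeloid call (0.4) or that numbered 3 oxidative phosphorylation (0.162). Without the NOD peptide array numbered 3, glycolysis (0.0876), chaperones (0.194) and myeloid markers (0.391) ended, and myeloid markers without that numbered 1 (0.0523).

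The third comparison asked whether the response differed between strains. No single gene did by limma: 0 probe sets were called, 0 with the replicate block, and 147 had an unadjusted p under 0.05, against 452 with the block. Pdcd1 gave a difference (NOD minus B6g7) of -1.11 ± 0.54 and Gadd45b, by its brighter probe set, -0.44 ± 0.41, each at adjusted p = 1. Activation receptors and cytokines responded less in NOD as a group (24 of 29 negative, median -0.19, camera adjusted p = 0.00116, and adjusted p = 0.575 with an estimated correlation). Myeloid and dendritic cell markers did so too (22 of 29 negative, median -0.20, adjusted p = 0.000101, and adjusted p = 0.575 with an estimated correlation). Both lists had 0 members passing over all genes or adjusted over the list alone, and the activation call was lost without the B6g7 peptide array numbered 3 (adjusted p = 0.0777). With the replicate block, double-positive thymocyte genes (median 0.20, adjusted p = 0.0309, against 0.0519 without it) and erythroid markers (median -0.18, 0.0461 against 0.0519) were called as well.

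Over Nr4a1, Gadd45b and Itm2a, the NOD response was 0.644 times that of B6g7 (exact permutation p = 0.06). The genes differed in this: Gadd45b, by its dimmer probe set, gave 0.40, while Itm2a gave 1.67 in NOD and 1.82 in B6g7, and the median ratio was 0.747. Without the dimmest 40% of probe sets, that of Gadd45b among them, the ratio was 0.821 (exact permutation p = 0.365). With strains exchanged only within replicate numbers, a choice made after seeing the data, the exact permutation p was 0.0312, the smallest that 64 assignments can give. Over 27 probe sets with an unadjusted p under 0.001 for the mean response, a set chosen after seeing the data, the ratio was 0.647 (exact permutation p = 0.145), with the response smaller in NOD for 22 of 27. In the interferon-response list, the B6g7 peptide array numbered 3 had a list mean of 8.39, against 6.71 and 6.42 in the other two of its group.

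The strain comparisons asked how NOD and B6g7 thymocytes differed in each setting. Without peptide, Cnn3 (calponin 3, an actin-binding protein) was lower in NOD, with 806 in B6g7 and 110 in NOD (log2 -2.87 ± 0.33, adjusted p = 0.00125). Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell from 302 to 101 (-1.58 ± 0.19, adjusted p = 0.00181). Slc1a5, a glutamine transporter, gave -1.17 ± 0.18 (0.0120) and Hat1, a histone acetyltransferase, -1.31 ± 0.19 (0.0089). Another probe set of Hat1 gave -0.62 and was not called. Higher in NOD were Hars, a histidyl-tRNA synthetase (2.26 ± 0.35, 0.0130), Pttg1 (securin, 1.24 ± 0.17, 0.00644) and Cd3g, the gamma chain of the CD3 complex (1.17 ± 0.22, from 799 to 1796, 0.0459). Each of Cnn3, Pdk1, Hars and Cd3g went the same way in 3 of 3 same-numbered pairs.

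The rule also named Gm3716 (1.35), Zfp982 (1.08), Bex4 (1.05) and Galnt11 (0.70) as higher in NOD, and Tmem14c (-2.58), Spg21 (-1.83), Kif23 (-1.56), 1700097N02Rik (-1.47), Ckb (-1.28), Agtrap (-1.11), Gemin5 (-0.93) and Gm11346 (-0.55) as lower. limma called 33 probe sets, 11 higher and 22 lower in NOD, with 428 at an unadjusted p under 0.05, and 69 with the replicate block. Leaving out 1 array gave 21, 17 and 16 without the B6g7 arrays numbered 1, 2 and 3, and 15 and 20 without the NOD arrays numbered 2 and 3. A fit of these 6 arrays alone called 0.

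At 16 h of peptide, Spg21 gave -2.68 ± 0.27 (adjusted p = 0.000532), Apoe, the apolipoprotein, -2.42 ± 0.36 (from 649 to 121, adjusted p = 0.0102) and Cd8b1, the CD8 beta chain, -2.02 ± 0.36 (from 1991 to 491, adjusted p = 0.0247), all lower in NOD in 3 of 3 pairs. Cd8b1 gave -1.89 without peptide, where it missed the threshold (adjusted p = 0.0519, and 0.0129 with the replicate block). Higher in NOD were Hars (1.89), the protease Capn3 (1.39 ± 0.24), Pqlc3 (1.29), Gm3716 (1.17), the chemokine receptor Cxcr4 (1.07 ± 0.20) and Bex4 (1.05). Tmem14c (-2.56), Mtif2 (-1.66) and Kif23 (-1.46) were lower. Gadd45b, by its dimmer probe set and named after its value was seen, was lower in NOD with peptide (-1.71 ± 0.33, adjusted p = 0.0391) and gave -0.13 without it. The gene's brighter probe set gave only -0.20 at 16 h and was not called.

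Of the probe sets at 16 h, limma called 61, 15 higher and 46 lower in NOD, with 705 at an unadjusted p under 0.05, and 129 with the replicate block. The count was 36 without the third-number arrays, 35 without the B6g7 array numbered 1, and 15, 31 and 22 without the NOD arrays numbered 1, 2 and 3. In wild-type cells, Cnn3 (-3.09 ± 0.40), Pdk1 (-2.08 ± 0.23), Hat1 (-1.61 ± 0.24), Agtrap (-1.42 ± 0.22) and Slc1a5 (-1.32 ± 0.22) were lower in NOD and Gm3716 (1.96 ± 0.18) was higher. With the replicate block limma called 32 probe sets there, 15 higher and 17 lower in NOD. Without the block it called 11 probe sets, 2 higher and 9 lower, with 259 at an unadjusted p under 0.05. This count fell to 2, 6, 4 and 7 without the B6g7 arrays numbered 1 and 2 and the NOD arrays numbered 1 and 2.

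The same probe sets recurred across the 3 settings, which share no arrays but share 1 spread per probe set in the fit. A probe set with a small spread is thereby favoured in every setting. The chance values below assume independent calls and may be too low. Of the 11 called in wild-type cells, 9 lower and 2 higher ones were also called without peptide, where chance gives 0.0159 and 0.00177, and the 33 called without peptide shared 16 lower and 9 higher ones with the 16 h set, where chance gives 0.0815 and 0.0133. In every setting 10 were called: Pdk1, Slc1a5, Hat1, Agtrap, Prdx2 and 3 probe sets with no gene name lower, and Gm3716 and AI506816 higher. Prdx2 and AI506816 were named after their values were seen, and their brighter probe sets gave 0.17 and -0.92 without peptide. Another probe set of Hat1 gave -0.62 without peptide, -0.37 at 16 h and -0.38 in wild-type cells, and was called in none of them. Of 69 probe sets called in at least 1 setting, 63 had the same sign in all 3 (46 lower and 17 higher in NOD).

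**Figure D4:**
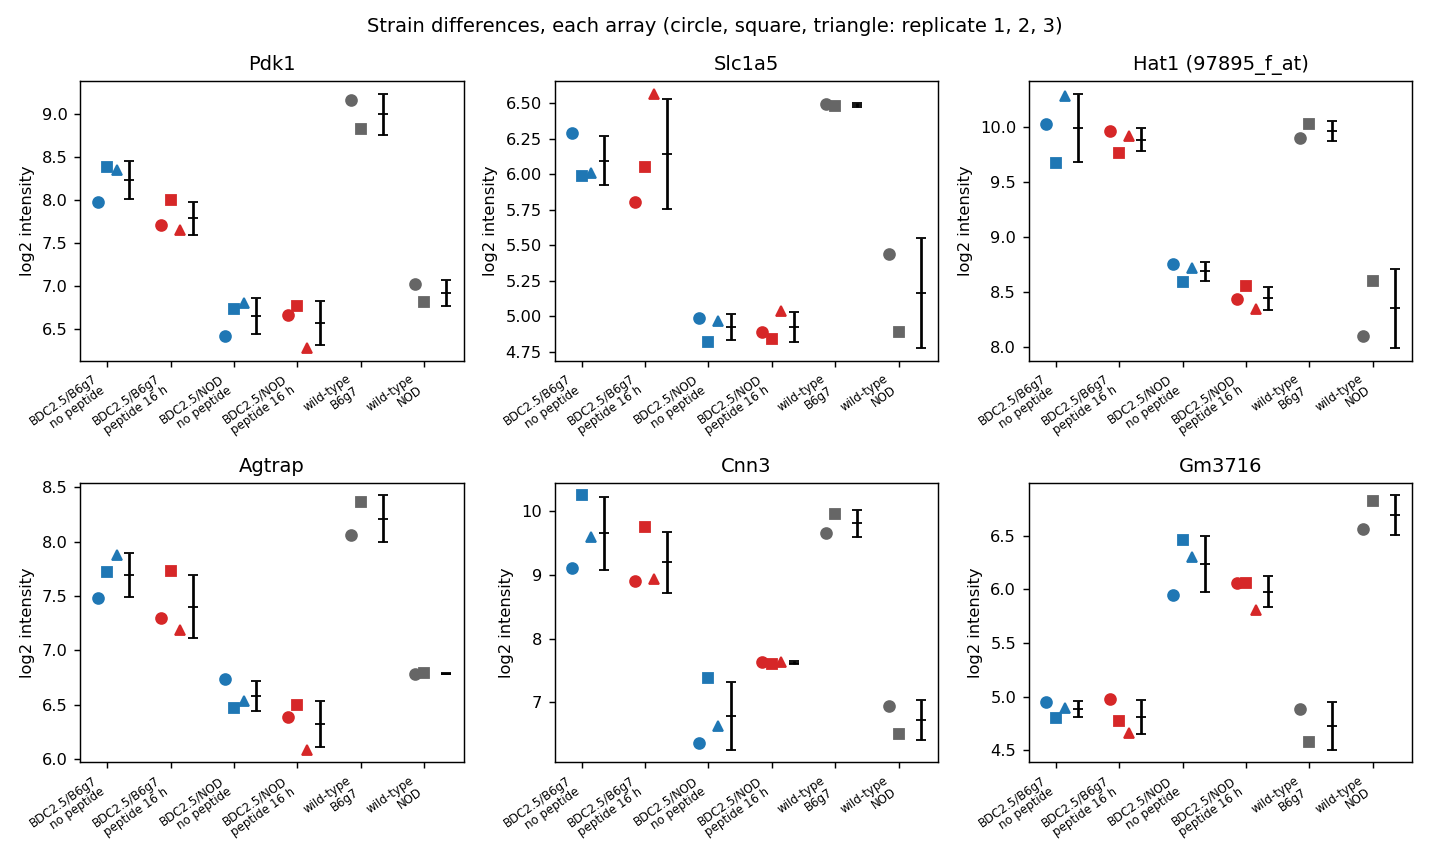
Each point is the log2 intensity of 1 array for Pdk1, Slc1a5, Hat1, Agtrap, Cnn3 and Gm3716 in the 6 groups, with the group mean ± SD beside it (n = 2 or 3). Pdk1 was lower in NOD than in B6g7 by -1.58 without peptide, -1.21 at 16 h and -2.08 in wild-type cells.

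As groups, interferon-response genes were lower in NOD without peptide (27 of 30, median -0.47, camera adjusted p = 2.41e-07, and adjusted p = 0.571 with an estimated correlation). At 16 h they were lower by the test as well (26 of 30, median -0.34, adjusted p = 0.00477, and 0.584 with an estimated correlation), but without the third-number arrays the median was 0.11. This list also moved with the third-number arrays themselves (median 0.62 higher there), as did chaperones (0.34) and cell cycle genes (0.14), with adjusted p = 0.129 to 0.58 with an estimated correlation. Without those arrays the chaperone calls with peptide in B6g7 (adjusted p = 0.012) and at 16 h (0.000586) held, as did the cell cycle calls with peptide in B6g7 (3.37e-07) and NOD (0.000942) and between strains without peptide (0.0315). Ribosome biogenesis genes were lower in NOD at 16 h (26 of 29, median -0.39, adjusted p = 3.24e-06, and 0.254 with an estimated correlation) and without peptide (21 of 29, adjusted p = 0.00351, and 0.571 with an estimated correlation). The other 2 calls without peptide were lower cell cycle genes (30 of 41, 0.00194) and lower maturation genes (16 of 25, 0.0299), each with adjusted p = 0.571 with an estimated correlation. Single arrays ended these 3 calls: ribosome biogenesis without the B6g7 array numbered 1 (0.0778) or the NOD array numbered 3 (0.236), cell cycle without the B6g7 array numbered 3 (0.351) or the NOD array numbered 1 (0.334), and maturation without the B6g7 arrays numbered 1 and 2 (0.0778 and 0.121) or the NOD arrays numbered 1 and 3 (0.168 and 0.3). At 16 h, interferon-response genes lost their call without the NOD array numbered 1 (0.0543) and ribosome biogenesis without the B6g7 array numbered 3 (0.0649). None of the 24 lists was called by camera in wild-type cells, where p53 targets had the lowest adjusted p = 0.21.

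At 16 h, 11 lists were called, none with an estimated correlation (adjusted p = 0.254 to 0.584). Activation receptors (22 of 29, 0.000565), myeloid (23 of 29, 0.000177), NK (9 of 11, 0.00276) and B cell markers (8 of 13, 0.0154) were lower in NOD, as were chaperones, glycolysis genes (each 0.00477) and NF-kB genes (0.0278). The kinase Blk (-1.38 ± 0.21, adjusted p = 0.0117) and Cd72 (-0.40 ± 0.08, adjusted p = 0.0425) were the 2 B cell markers called over all genes. p53 targets (11 of 13, 0.0018), with Cdkn1a (p21) at 0.91, and TCR proximal signalling genes (16 of 20, 0.0189), with Cd3g at 0.93, were higher in NOD. Without the B6g7 array numbered 3 the calls of activation receptors (0.0649), NF-kB (0.723), glycolysis (0.723), chaperones (0.363) and TCR proximal genes (0.052) were lost. NF-kB genes (0.145) and chaperones (0.0543) also lost theirs without the NOD array numbered 1, and chaperones (0.181) and B cell markers (0.0551) without the NOD array numbered 2. B cell markers did so without the B6g7 array numbered 2 (0.0867), and TCR proximal genes without the B6g7 array numbered 1 (0.113) or the NOD array numbered 3 (0.0504).

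The transgene comparisons asked how BDC2.5 thymocytes without peptide differed from wild-type ones. Probe sets of TCR segments were read as well. No segment was predicted beforehand for the transgenes, so a rise of a given segment does not check the labels. In B6g7, probe sets of the alpha-chain segment Trav9d-3 were higher in BDC2.5 cells (2.60 ± 0.26 by the brightest, adjusted p = 0.000445, and 3.24 ± 0.34 by another), while the dimmest gave 0.08. The beta-chain segment Trbv13-2 was lower (-2.81 ± 0.27, from 279 to 39.9, adjusted p = 0.000388), as was Trbv1 by a dimmer probe set (-1.81), whose brighter probe set gave 0.30. Gimap4, a GTPase gene of maturing T cells, rose from 127 to 814 (2.68 ± 0.34, adjusted p = 0.00263) and the histone chaperone gene Asf1b from 271 to 1196 (2.14 ± 0.25, adjusted p = 0.00124). In NOD, Asf1b (1.97 ± 0.25, adjusted p = 0.00645) and Trbv13-2 (-2.30 ± 0.27, adjusted p = 0.00557) changed the same way, Trbv1 gave -1.24 and Trav9d-3 1.19 ± 0.26 (adjusted p = 0.676). Segment probe sets may bind related segments, which was not tested, and those outside each gene's brightest were named after their values were seen.

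limma called 10 probe sets in B6g7 (5 higher, 5 lower, 185 at an unadjusted p under 0.05) and 7 in NOD (1 higher, 6 lower, 248). In B6g7 the count was 6 without the wild-type array numbered 1. In NOD it was 2 and 4 without the wild-type arrays numbered 1 and 2, 4 without either BDC2.5 array numbered 2 or 3, and 0 without the third-number arrays. Maturation genes were higher in BDC2.5 cells of B6g7 (19 of 25, median 0.12, adjusted p = 2e-07, and 0.0178 with an estimated correlation) and of NOD (17 of 25, median 0.18, adjusted p = 0.0132, and 0.342 with an estimated correlation). Double-positive genes were lower in both (adjusted p = 0.0111 and 0.0132, and 0.507 and 0.342 with an estimated correlation). Maturation genes in B6g7 kept their call without any 1 array. In NOD they lost it without the BDC2.5 arrays numbered 2 (0.287) and 3 (0.0508) and the wild-type arrays numbered 1 (0.2) and 2 (0.0885). Double-positive genes lost theirs without the BDC2.5 array numbered 1 (0.486 in B6g7, 0.369 in NOD) or the wild-type array numbered 2 (0.502 and 0.737). Without the third-number arrays, maturation genes kept their call in B6g7 (2.79e-14) and NOD (0.000613) and double-positive genes in B6g7 (0.0197) but not in NOD (0.168). Double-positive genes had a median 0.18 higher on those arrays, without a call (adjusted p = 0.119), and the imbalance between 1 of 2 wild-type and 1 of 3 BDC2.5 arrays pulls in the direction of their fall.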

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

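The tests of the array structure, the strain calls and the smaller NOD response were chosen only after those results were seen, except the test of other cell types, the free permutation of strains (p = 0.06), the slopes with 1 array left out and the counts over other splits of the arrays (the 32 splits that part every pair were added later).

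Activation receptors and cytokines, and myeloid and dendritic cell markers, stood out because their peptide response differed between the strains. The median difference (NOD minus B6g7) was -0.19 for the activation list (24 of 29 members negative) and -0.20 for the myeloid list (22 of 29). With an estimated correlation both had adjusted p = 0.575, and no single member was called.

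For the mean response of Nr4a1, Gadd45b and Itm2a, a chance split of the arrays is argued against but not excluded. Of 100 splits of the arrays, 1, the real one, gave as many as 3 called probe sets, and the highest other gave 0. Those splits were drawn without regard to the same-numbered pairs, which deviate together. Among the 32 splits that part every same-numbered pair, the real one alone reached its count (3, and 7 with the replicate block), and the highest other was 0 in both fits. The count itself was 0 without either of 2 single arrays, and 1 (Itm2a) with the block within each strain, where Nr4a1 and Gadd45b had adjusted p = 0.125. For the difference between the responses and for peptide in NOD the real count was 0, which every split reaches (100 of 100 and 10 of 10), so the splits test nothing there. Of the other 99 splits for the difference, 3 had any call, and the highest called 119, which points to a structure of the samples. The strain difference can be that structure, since a split that turns the strains at only 1 peptide state tests the sum of both strain differences. Whether the split with 119 calls was of that kind was not recorded. For 3 against 3 arrays, 10 splits are too few for a share under 0.05. There the real and highest other counts were 1 and 0 (peptide in B6g7, 1 of 10 splits as large), 0 and 0 (peptide in NOD, 10 of 10), 33 and 0 (strain without peptide, 1 of 10) and 61 and 2 (strain at 16 h, 1 of 10). Among the 4 splits that part every same-numbered pair, the highest other count was 0 in each.

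The third-number arrays (the BDC2.5 arrays numbered 3 and wild-type arrays numbered 2) stood apart, with Xist 3.01 ± 0.96 higher and Mxd4 at -1.67. More degraded RNA in these 6 arrays is argued against, since the Gapdh 3' minus 5' signal was lower there by -0.66, where degradation needs it higher. More degraded RNA in the other 10 arrays would give the same values, so RNA quality as the source stays open. For other cell types, the largest median shift of their 6 marker lists was -0.14. This argues only against a shift of most members of a list, since a median does not follow a few members or markers with little signal. Less 3' bias met its test (actin -1.01, exact permutation p = 0.00309, the smallest possible), which reads the same kind of signal as the degradation test. A different RNA preparation or labelling batch may be the source. Sex of the thymus donors stays open: over 16 arrays, Xist and the first component correlated within groups at Pearson r = 0.587 (permutation p = 0.0519, BH 0.104 over 2 genes) and Spearman 0.544 (permutation p = 0.0719), and r was 0.665 without the 2 farthest arrays, while Eif2s3y gave Pearson -0.03 (permutation p = 0.934, BH 0.934), Spearman 0.129 (permutation p = 0.663) and -0.14 without the 2 farthest, where sex as the cause predicted a correlation for both genes.

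Most strain calls, such as Pdk1, Cnn3 and Slc1a5, were lower in NOD (46 of the 63 with 1 sign in every setting), but with the replicate block the wild-type calls were 17 lower and 15 higher. That block grouped the wild-type arrays numbered 2 with the BDC2.5 arrays numbered 2, with which they did not deviate together. A general loss of signal could not be tested, since the authors' scaling holds the medians of the arrays together (lowest median of all probe sets -0.0264). A sequence variant of NOD under the probe sets cannot be told apart from lower expression. In 16 genes the other probe sets showed a median share of 0.0343 of the called change (bootstrap 95% -0.113 to 0.26), against 0.264 (0.213 to 0.318) in 397 comparison genes. In the 12 of the 16 that were lower in NOD the median share was 0.106, with no interval computed. Strain biology stays open and was not tested.

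The peptide response of Nr4a1, Gadd45b and Itm2a was smaller in NOD. A single array as the cause of a ratio below 1 is argued against, the highest ratio with 1 array left out being 0.722. These ratios kept the probe sets chosen with all arrays, and no p was computed for them. A higher starting level in NOD was not seen, since 17 of 20 rising probe sets started lower there (median -0.11, bootstrap over probe sets -0.19 to -0.05). These probe sets were read on the same arrays, so the interval does not measure the spread between arrays. Chance assignment of arrays to strains stays open: exact permutation p was 0.06 with arrays exchanged freely, the test fixed in advance, and 0.0312 with arrays exchanged only within replicate numbers, the smallest that 64 assignments can give. No biological explanation was tested, and a weaker response of NOD thymocytes remains a hypothesis.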

How the results depend on the processing

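The third-number block, the third-number arrays left out, the Xist and Eif2s3y covariates, the ratio over 27 probe sets, the exchange of strains within replicate numbers and, for lists, the replicate block and single arrays left out were tests chosen only after the data were seen.

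Over all alternatives, 1941 values of single named genes kept their side of the threshold, 472 became weaker, 4 stronger and 24 changed sign without a call, with 0 called values reversed. The cause was not tested for any change below, except that fewer arrays were fitted where groups or arrays were left out.

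For peptide in B6g7, the count of 1 became 0 without the dimmest probe sets, 2 with quantile normalization, 2 with log2(value + 32), 0 with no intensity trend, 27 with array weights, 3 with the replicate block, 0 with the block within each strain, 3 with the third-number block, 3 with those arrays left out and 0 with only its own groups. For the mean response, 3 became 8 with array weights, 7 with the replicate block, 1 with the block within each strain and 6 with the third-number block. The counts of 0 for peptide in NOD and for the difference stayed 0 in limma without any 1 array.

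The strain counts with array weights were 63 without peptide and 362 at 16 h. With the replicate block they were 69 (46 lower in NOD), 129 (84 lower) and, in wild-type cells, 32 (17 lower and 15 higher, against 9 and 2 without the block), where the 2 same-numbered deviations correlated at 0.810. With the third-number block they were 114, 183 and 48, and with only their own groups 0, 22 and 0. At 16 h the third-number arrays left out gave 36. The transgene count in B6g7 was 16 with array weights and 1 with only its groups. In NOD it was 0 without the third-number arrays, 3 with the covariates and 0 with only its groups. The replicate block changed no other count by more than 1.5 times.

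Lists called with an estimated correlation numbered 0 and 2 for peptide in B6g7 and NOD, 0 for the difference, 5 for the mean, 0 for strain without peptide and at 16 h, and 1 and 0 for the transgene in B6g7 and NOD. The counts that follow were made with the preset correlation instead. Lists called without the third-number arrays numbered 5 (peptide in NOD), 5 (difference), 6 (mean) and 2 (strain without peptide). Without the dimmest probe sets they were 4 (difference) and 7 (strain at 16 h), with the replicate block 4 (difference) and 1 (wild-type strain), and with quantile normalization 1 (wild-type strain).

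The response ratio was 0.636 with quantile normalization (exact permutation p = 0.035) and 0.40 over Gadd45b, the 1 probe set called in either strain, whose choice for passing in B6g7 favours a ratio below 1. With strains exchanged within replicate numbers it stayed 0.644 (exact permutation p = 0.0312, the smallest possible). Without the dimmest probe sets it was 0.821 (exact permutation p = 0.365), with median centring 0.660 (0.07), with log2(value + 32) 0.680 (0.085) and over 27 probe sets 0.647 (0.145), so its call depended on the setting. It was 0.559 to 0.722 with 1 array left out.

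With 1 array left out, counts ran from 0 to 10 (peptide in B6g7), 0 to 10 (mean), 15 to 24 (strain without peptide), 15 to 42 (16 h), 2 to 7 (wild-type), 6 to 8 and 2 to 5 (transgene in B6g7 and NOD). List counts ran from 11 to 15 and 6 to 10 (peptide in B6g7 and NOD), 2 to 7 (difference), 8 to 14 (mean), 2 to 6, 5 to 11 and 1 to 2 (strain without peptide, 16 h, wild-type), 5 to 8 and 1 to 6 (transgene). Where a wild-type group kept 1 array, that array was assumed to vary like the other groups. Low signal over background limits dim probe sets.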

Other observations

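The tests given in this part, the comparison of the third-number arrays with the rest, the permutations of the interferon list mean and the lists without the third-number arrays, were chosen only after the data were seen.

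Transcripts of sex-linked genes varied between arrays of the same group. Xist ran from 12.9 to 1815 and the Y-linked Eif2s3y from 21.6 to 270, and wild-type NOD array 2 had 1028 and 240.

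Against the other 10 arrays, the 6 third-number arrays had 4091 of 12422 probe sets called by limma, 1839 higher and 2252 lower. Ss18 (2.54), Septin7 (2.46) and the RNA helicase Ddx5 (2.39) were among the higher and Sdhb (-1.49) among the lower.

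The mean of the interferon-response list varied within groups with an SD of 0.570. The B6g7 peptide array numbered 3 weighed on this SD and on the B6g7 peptide mean, with 8.39 against 6.71 and 6.42 in the rest of its group. The list mean shifted by 0.27 and 0.40 with peptide in B6g7 and NOD, and by -0.53 and -0.40 between strains without peptide and at 16 h. Exact permutation gave p = 1, 0.1, 0.1 and 0.9, where 0.1 is the smallest possible with 3 against 3 arrays.

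In BDC2.5 cells of B6g7 without peptide against wild-type cells, the remaining called lists were TCR immediate-early (adjusted p = 0.00101), ribosome biogenesis (0.00729), glycolysis and oxidative phosphorylation (each 0.0111), with adjusted p = 0.286 to 0.507 with an estimated correlation. In NOD, double-negative genes, p53 targets, interferon-response genes, glycolysis genes and chaperones were called lower (each adjusted p = 0.0132, and 0.342 to 0.907 with an estimated correlation), and each lost its call without at least 1 array, as did the B6g7 lists just named. The third-number arrays weigh more in the wild-type groups (1 of 2 arrays against 1 of 3), an imbalance that pulls down lists higher on them. Interferon-response genes (median 0.62, adjusted p = 0.000421) and chaperones (0.34, 6.4e-07) were called higher there, with adjusted p = 0.58 and 0.129 with an estimated correlation, while p53 targets (0.23, 0.11) and double-positive genes (0.18, 0.119) had no call. Without those arrays the NOD calls of these 4 lists ended (adjusted p = 0.529, 0.799, 0.216 and 0.168), while those of double-negative (0.000613) and glycolysis genes (0.0106) held. In the mean response, 7 of the 8 calls lost with an estimated correlation also ended when the third-number arrays were left out, the exception being chaperones (0.0159).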
